A study of Homo sapiens with 4 samples.

How the data were processed

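RNA abundance was measured on 4 one-colour Agilent expression arrays, each hybridised with Cy3-marked RNA of a human ovarian clear cell adenocarcinoma line, KOC-7C or TOV21G. Per the labels, cells received CBX7 siRNA or control siRNA at 10 nM with a lipid transfection reagent, and total RNA was taken 48 h later. The 4 groups (2 lines, 2 siRNAs) held 1 array each, so a difference within a line has no replicate check, and the number of arrays limits the precision of every value. The number of siRNA sequences and of cultures behind each RNA sample was not analysed here. All 4 arrays lay on 1 slide and were read in 1 scan, so slide and scan did not separate the groups. Batches of culture, RNA extraction and labelling were not analysed here.

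Per the file headers, the authors read spot intensity with Agilent Feature Extraction 10.7, which subtracted background and removed spatial trends within each array, and the probe positions refer to hg19. The deposited intensity values were not scaled between arrays. The deposited value table holds log2 values, and their scaling was worked out from the values. Set against the scanner values over 42395 probes, each of its columns equalled log2 of the processed intensity minus a constant (r = 1 and slope 1 on each array). The constant, 9.31, 8.46, 9.31 and 8.73 in the order KOC-7C control, KOC-7C CBX7, TOV21G control and TOV21G CBX7 siRNA, lay close to the array's own 75th percentile of the log2 signal (9.33, 8.47, 9.32 and 8.74). The medians of the columns were -4.08, -4.07, -3.99 and -3.90, and genes were not centred.

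From the scanner files, spots marked as non-uniform or as population outliers (217 to 418 of 58717 non-control spots per array) were left out, and no spot was saturated. Log2 processed signals were averaged over the spots of a probe, and each array's 75th percentile was subtracted. Of 42405 non-control probes, 42395 had a value on every array. Probe names were updated through a RefSeq gene table of the GRCh38.p14 assembly, used for names only. It held 26358 of the 27241 probes with a RefSeq accession, and 13263 probes kept the name in the array files. Where a gene had several probes (7184 of 32570 genes and transcripts), the probe with the highest mean signal over the 4 arrays stood for it. Coordinates are those of the array files on hg19. An hg19 annotation was not used here, so exons and untranslated regions are not given.

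Signal over background set which genes could be compared. A gene was measured in a line if its probe was well above background on both arrays, and a probe was so when no fewer of its spots were marked well above background than not. The share of probes well above background was 57.8% on the KOC-7C control array, 52.6% on the KOC-7C CBX7 siRNA array, 60.7% on the TOV21G control array and 57.1% on the TOV21G CBX7 siRNA array. The array's 75th percentile of signal was 643, 355, 641 and 428 in that order. Where all probes of a gene were above background on only 1 of the arrays of a line, the brighter array was set against the higher of the dim probe's own signal and the array's lowest signal well above background, which gives a bound written as "at least". The median SD of log2 signal between repeat spots of a probe (probes with at least 5 spots) was 0.06 on every array. It covers measurement on the array and leaves out culture, labelling and hybridisation. The 10 E1A spike-in probes had a median signal of 3.19 to 3.80, below the lowest signal well above background on each array (13.0 to 14.8), so they could not serve for scaling.

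Within a line, log2 differences (CBX7 siRNA minus control siRNA) and counts of genes at least 2-fold apart were computed with no test. Across both lines, limma 3.58.1 (R 4.3.3; lmFit and eBayes) was fitted to all 4 arrays with cell line as a block, since the lines are the pairs of the design. It used the 19616 genes well above background on at least 2 arrays and called genes at a Benjamini-Hochberg adjusted p under 0.05. The fit left 1 residual degree of freedom and borrowed the rest from other genes (prior degrees of freedom 54.8). Its p-values treat the lines as replicates of the siRNA contrast. A simulation of 19616 genes on the same design drew independent noise from the prior fitted to these arrays. There limma recovered 14.9% of 67 genes changed by 1 on the log2 scale. It recovered 82.1% of 67 changed by 2 and 100% of 66 changed by 3, and 16 of 147 calls were false. The simulation held no effect of a single array such as low 5' signal, so these rates may not hold for the calls on the real arrays. The agreement of the lines was described over the 16928 genes well above background on all 4 arrays.

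Gene lists (31 lists, 779 symbols) were described by the median log2 difference of their measured members. Beside it stands its percentile among 10000 random lists of the same size, matched on mean signal in 20 bins, as a description of these arrays. The results text describes all of the lists but 1. On the TOV21G values, 20 of 20 lists of 30 random genes shifted by 0.5 lay above the central 95% of random lists, and 2 of 20 unshifted lists lay outside it. Probes at the 5' and 3' ends of the same gene were compared for 2964 genes, with a 95% bootstrap interval from 2000 resamples. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

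The tests, the 31 lists, the rule for named genes and the alternative settings were chosen before the data were examined. The rule named CBX7 and TNFSF10, the 8 highest and 8 lowest measured genes of each line, the 10 genes higher and the 10 lower in both lines by the smaller of their differences, the 5 with the largest opposite differences, and up to 4 members of each list by mean difference (153 genes). TNFSF10 and the TRAIL and death receptor list were put in from prior knowledge of published work on CBX7 in clear cell carcinoma and not from the labels, so they were not a blind choice. Any other gene was named after its values were seen. Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, scaling by the median, other filters on dim probes, the mean of all probes of a gene, a floor, the deposited value table, other fold thresholds, limma without the block, with a trended or robust prior, and with each array left out. The probe nearest the 3' end of each gene and 7 further gene lists were added after the data were seen. Genes not above background on any array, control probes and names without an approved-style symbol were left out of the named genes.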

Results

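CBX7 is a chromodomain protein of Polycomb repressive complex 1, which binds methylated histone H3 and keeps genes silent. The series asked which transcripts differ when CBX7 is knocked down in ovarian clear cell adenocarcinoma cells, a histological type of ovarian cancer. KOC-7C and TOV21G, established lines of this type, were transfected with CBX7 siRNA or control siRNA, and RNA taken 48 h later was measured on 4 arrays, 1 for each line and siRNA. With 1 array per group, values within a line carry no replicate error. Values are log2 signals relative to each array's 75th percentile, and differences are CBX7 siRNA minus control siRNA. Of the 4 arrays, the KOC-7C CBX7 siRNA array had the lowest 75th percentile of signal, 355 against 643 on its control, and TOV21G had 428 against 641. On the KOC-7C CBX7 siRNA array, probes further 5' in a gene read lower relative to those further 3', called low 5' signal below. Over 2964 genes, the difference at the most 5' probe minus that at the most 3' probe had a median of -0.48 in KOC-7C (95% bootstrap interval -0.51 to -0.44). In TOV21G it was -0.12. How near these probes lay to the transcript's ends was not checked. The 4 probes for 28S ribosomal RNA were between -4.07 and -8.53 in KOC-7C and between 0.39 and 0.55 in TOV21G.

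The knocked-down gene was read first, since it checks the labels. CBX7 signal at its brighter probe (chromosome 22, 39527000 to 39527059, minus strand, hg19) was 0.38 on the KOC-7C control array and -0.98 on the KOC-7C CBX7 siRNA array, a difference of -1.35 or 2.55-fold. In TOV21G it was -0.12 under control siRNA and -1.40 under CBX7 siRNA, a difference of -1.28 or 2.43-fold. Across both lines the mean difference was -1.32 (SE 0.42, limma adjusted p = 0.0696), short of the threshold. The other CBX7 probe, 2719 bp away toward the 5' end (39529719 to 39529778), differed by -0.56 in KOC-7C and 0.17 in TOV21G, so the lower CBX7 signal in TOV21G rested on the brighter probe. TNFSF10, which encodes the death ligand TRAIL and was picked from prior knowledge of work on CBX7 in this tumour type, rose across both lines by a mean of 3.56, or 11.8-fold (SE 0.43, limma adjusted p = 1.74e-08). Its difference was 4.09 (17.1-fold) in KOC-7C and 3.02 (8.13-fold) in TOV21G at the probe on chromosome 3, 172223866 to 172223925. Its other probe was 20.4-fold higher in KOC-7C and 10.5-fold in TOV21G. The limma p-values here and below rest on 1 residual degree of freedom and a prior drawn from other genes. Under quantile normalization no gene passed, TNFSF10 included.

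**Figure D1:**
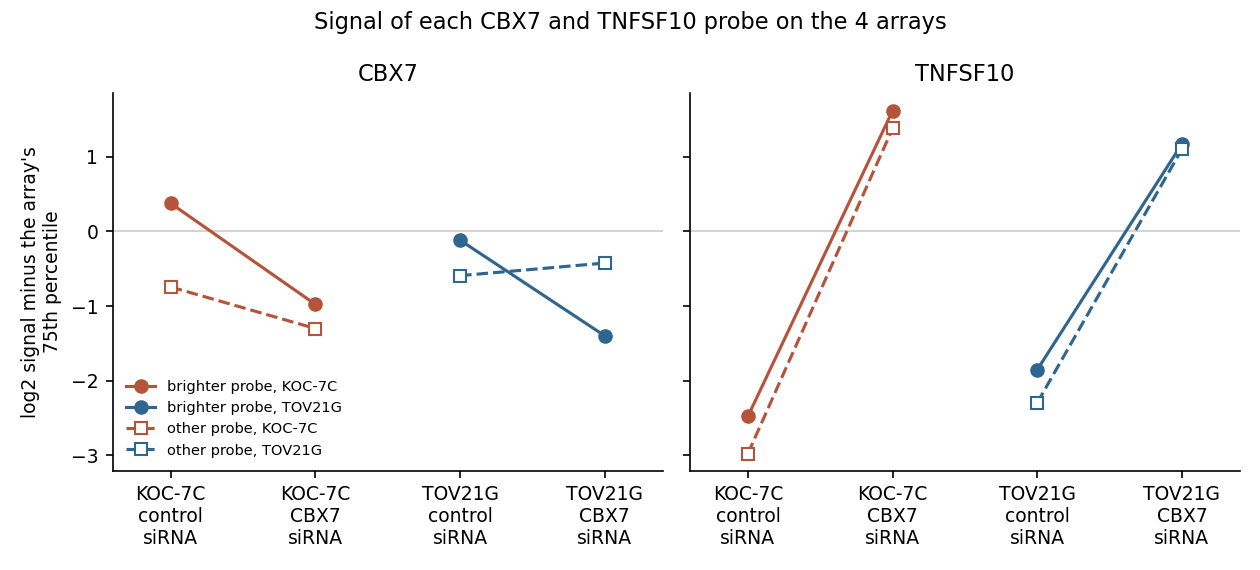
Log2 signal of each CBX7 and TNFSF10 probe, relative to the array's 75th percentile, on the 4 arrays (1 per group, lines join the arrays of a cell line). Both TNFSF10 probes were higher with CBX7 siRNA in both lines, whereas the other CBX7 probe differed by -0.56 in KOC-7C and 0.17 in TOV21G.

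To find what the lines had in common, the siRNA contrast was fitted across all 4 arrays with cell line as a block. The genes that rose included several of antiviral and inflammatory responses. Among them were MX2, an interferon-induced antiviral GTPase (mean difference 4.25, SE 0.43, limma adjusted p = 6.22e-11, at the brighter probe alone, as its other probe gave 0.34 in KOC-7C and -0.04 in TOV21G), CCL5, a chemokine that draws T cells (4.70), the acute phase proteins SAA2 (5.71) and SAA1 (4.99), and IL18BP, which neutralises interleukin-18 (3.94). GSDMB, a pore-forming gasdermin, rose by 5.18, IGFBP6, a binding protein of insulin-like growth factors, by 4.04, and LGALS9C, a galectin, by 4.31. ACKR4, an atypical chemokine receptor, rose too, with a difference of 4.44 in TOV21G and at least 5.33 in KOC-7C, where its control signal lay under the array's lowest signal well above background. The cancer-testis genes CSAG1 and CSAG2 rose by 4.51 and 4.85. Each of these was at least 11.8-fold higher in both lines, apart from SAA1, which was 10.4-fold higher in TOV21G.

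Fewer genes fell in both lines, and by less. ACO1, the cytosolic aconitase that doubles as an iron sensor, had a difference of -2.05 in KOC-7C and was 4.01-fold lower in TOV21G (mean difference -2.02, SE 0.42, limma adjusted p = 0.0013). The long non-coding RNA DANCR had a mean difference of -1.87, the adenosine receptor gene ADORA1 -2.13, the membrane protein gene SMAGP -1.91, the oxidative stress gene OSGIN1 -1.90, SMLR1 -1.63 and SCIN, an actin-severing protein, -1.45. The glutathione transferases GSTA5 and GSTA2 had mean differences of -1.78 and -1.66. GSTA2, GSTA5, SAA1, SAA2, CSAG1, CSAG2 and LGALS9C belong to families of near-identical copies, and their probes were not checked for signal shared between copies. The same holds for HSPA1A, HSPA1B, IFNL2 and IFNL3, named below.

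limma called 494 genes higher and 237 lower of 19616. Of the 494, 493 had the same sign in both lines and 396 were at least 2-fold higher in each. Of the 237, 169 had the same sign and 56 were at least 2-fold lower in each. Their median difference was -3.26 in KOC-7C, the line whose CBX7 siRNA array had low 5' signal, and -0.38 in TOV21G. No gene passed under quantile normalization, where 1172 genes higher and 623 lower had an unadjusted p under 0.05. Likewise none passed without the cell line block (653 higher and 141 lower at an unadjusted p under 0.05). Fits that left out an array also dropped the block, so they are no separate check of dependence on single arrays.

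Genes induced by interferon stood out among the 31 lists fixed in advance. In KOC-7C the 39 measured members had a median difference of 1.55 (2.92-fold), with 29 at least 2-fold higher, 1 at least 2-fold lower and 35 above 0, and in TOV21G 0.94 (1.92-fold), with 19 at least 2-fold higher and all 39 above 0. None of 10000 random lists reached these medians (percentile 100 in each line). In the fit over both lines, 19 of 39 members rose (28 adjusted over the list alone) and none fell. IFIT2 (mean difference 3.38), HERC5 (3.21), OASL (3.14) and RSAD2 were among them. IRF9, a transcription factor of the interferon response, differed by -0.07 in KOC-7C and 0.32 in TOV21G and did not pass. In KOC-7C, where the array had low 5' signal, IFI6 (-2.44 against 1.76 in TOV21G), OAS3 (-0.68) and IFI35 (-0.14) also went against the list.

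MHC class I antigen presentation genes, which load and display peptides at the cell surface, were higher in both lines. The median over 17 members was 1.43 in KOC-7C (2.69-fold) and 1.99-fold in TOV21G (percentile 100 in each), and 8 members rose in limma's fit (11 adjusted over the list alone). B2M, the shared light chain, had a mean difference of 2.07, HLA-F 2.19, HLA-C 1.89 and the immunoproteasome subunit PSMB9 1.89. Inflammatory cytokines and NF-kB targets had a median of 2.07 in KOC-7C over 21 members and 0.41 in TOV21G over 22, above random lists in both (percentile 100). Of 22 tested members 10 rose (14 adjusted over the list alone), among them SOCS3 (4.38 in KOC-7C and 0.88 in TOV21G), CXCL10 (4.17 and 0.98), IL6 (4.30 and 0.60) and CCL20 (3.16 and 1.29). CXCL3 was 2.07 in KOC-7C and -0.97 in TOV21G. The KOC-7C values of these 2 groups come from the array with low 5' signal.

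**Figure D2:**
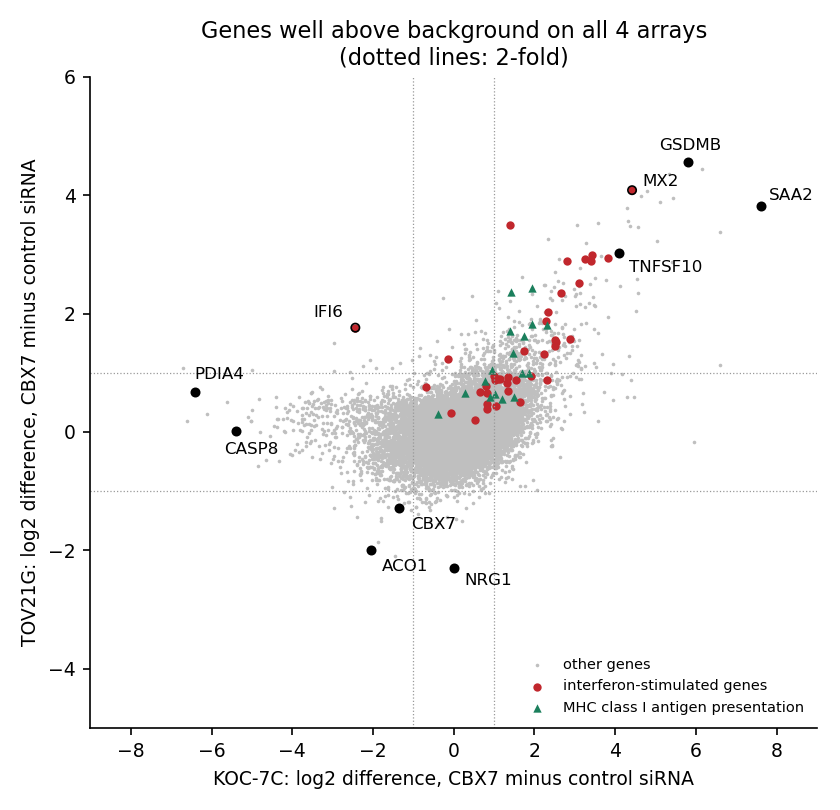
Log2 difference (CBX7 minus control siRNA) in KOC-7C on the horizontal axis and in TOV21G on the vertical axis for each of the 16928 genes well above background on all 4 arrays, with interferon-stimulated and MHC class I genes in colour. Across genes r was 0.39, and GSDMB and TNFSF10 lay high in both lines. PDIA4, CASP8 and the interferon-stimulated gene IFI6 were low in KOC-7C alone among the genes named.

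Genes of cell death were mixed. The TRAIL and death receptor list had medians of 0.59 in KOC-7C and 0.01 in TOV21G (percentiles 83.2 and 61.9), the latter turning to -0.09 under scaling by the median. Of its 19 tested members, TNFSF10 and TNFRSF25, a death receptor (mean difference 1.53), rose, and CASP8, the initiator caspase, fell by 2.68 (the counts over all genes and adjusted over the list alone were both 2 higher and 1 lower). The TRAIL receptors TNFRSF10A (-1.23 in KOC-7C and -0.72 in TOV21G) and TNFRSF10B (0.35 and -0.47) were not called. The fall of CASP8 came from KOC-7C alone (-5.39 against 0.02 in TOV21G), on the array with low 5' signal, where its other probe gave -1.39. In the BCL2 family and mitochondrial apoptosis list (medians 0.67 and 0.26, percentiles 96.7 and 99.8) 3 of 23 members rose (3 adjusted over the list alone, and 1 lower). These were the BH3-only genes PMAIP1 (3.48 in KOC-7C and 1.17 in TOV21G) and BCL2L11 (mean 1.52, with other probes at -0.24 and -0.57 in KOC-7C and 0.38 and 0.96 in TOV21G) and the caspase inhibitor BIRC3 (3.16 and 1.08). The p53 target genes had medians of 0.13 in KOC-7C, turning to -0.14 under quantile normalization, and -0.23 in TOV21G (percentiles 17.3 and 0.53, the latter below random lists). Among 25 tested members 2 fell (3 adjusted over the list alone) and none rose. They were the CDK inhibitor CDKN1A (-2.14 and -0.94) and ZMAT3, below background on an array of KOC-7C and -0.79 in TOV21G.

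Over their measured members, Polycomb lists had no common direction in the lines. A target below background under control siRNA was not measured, even if it rose with CBX7 siRNA, so the medians leave out such genes. Of 39 HOX genes on the array, 25 were measured in KOC-7C and 27 in TOV21G. For 49 other developmental factors these numbers were 25 and 28. The 23 members of Polycomb repressive complex 1 had medians of 0.17 in KOC-7C and -0.10 in TOV21G (percentiles 45.6 and 10.6). None passed over all genes. Adjusted over the list alone 1 was higher, PHC3 (1.71 in KOC-7C and 0.90 in TOV21G), and 1 lower, the siRNA target CBX7 itself. The paralogue CBX6 differed by -0.81 and -0.86 and did not pass. The HOX genes, classic Polycomb targets, had medians of 0.15 over 25 members and 0.10 over 27 (percentiles 33.1 and 83.8), and no HOX gene passed over all genes or adjusted over the list alone. The KOC-7C HOX median turned to -0.30 under quantile normalization. HOXA2 was 1.15 and 1.17, and HOXD8 -1.70 and -0.94. Other developmental transcription factors under Polycomb control had a median of 0.31 in KOC-7C and -0.20 in TOV21G (percentiles 68.1 and 0.45, the latter below random lists), and 2 of 30 fell (2 adjusted over the list alone) with none higher. They were the cardiac factor NKX2-5 (-3.98 in KOC-7C, on the array with low 5' signal, and 0.44 in TOV21G) and LHX9, which was not well above background on both arrays of either line. Of the INK4 genes, CDKN2A differed by 0.52 and 0.46, CDKN2C by 0.54 and 0.54 and CDKN2D by 0.25 and -0.27, and none passed. CDKN2B was not well above background on both arrays of either line and was not tested.

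In TOV21G cholesterol and sterol synthesis genes had a median of 0.35 (24 members, percentile 100; 0.66 and percentile 93.2 in KOC-7C), led by INSIG1, which rose across both lines (1.72 in KOC-7C and 1.51 in TOV21G) and was the 1 member called, over all genes and adjusted over the list alone. Genes of the mitochondrial respiratory chain lay below random lists in both lines, at 0.24 in KOC-7C, turning to -0.23 under quantile normalization, and -0.09 in TOV21G (46 members, percentiles 0.02 and 1.55), and none passed. With the probe nearest the 3' end of each gene, or with no filter on background, the list no longer lay below random lists in both lines. Glycolysis and hypoxia genes had medians of 0.80 and 0.16 (27 members, percentiles 99.6 and 95.3), with BNIP3L at 1.72 and 1.03 (another of its probes gave -0.08 and 0.18), and none passed. DNA replication (33 members, medians 0.42 and -0.03) and mitosis genes (35 members, 0.50 and -0.13) held no member that passed. Ribosomal protein genes had medians of 0.61 and 0.11, which turned to -0.01 and -0.10 under quantile normalization. Replication-dependent histones went apart, at -0.25 in KOC-7C and 0.22 in TOV21G (32 members, percentiles 0.01 and 99.97), with H3C2 at -2.60 and 0.02, and the low histone values sat on the array with low 5' signal.

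Of the remaining lists, the stress genes NUPR1 and TRIB3 rose within the ATF4 and amino acid response list (medians 0.45 in KOC-7C and -0.03 in TOV21G, 2 of 26, 3 adjusted over the list alone), with mean differences of 2.10 and 2.17. Among epithelial adhesion genes and keratins CDH1, the E-cadherin gene, rose, at 2.13 in KOC-7C and 1.87 in TOV21G (list medians 0.79 and 0.21, percentiles 98.3 and 97.3, 1 of 19 members, 3 adjusted over the list alone). In the mesenchymal and extracellular matrix list, with medians of 0.40 and 0.02, the latter turning to -0.08 under scaling by the median, 2 of 19 rose (2 adjusted over the list alone), the collagenase gene MMP1 and the collagen gene COL1A1, the latter not well above background on both arrays of either line. Immediate early genes had medians of 0.60 in KOC-7C and -0.18 in TOV21G (percentiles 94.1 and 2.81), and 2 of 23 rose (5 adjusted over the list alone), DUSP1 and IER3. NRF2 targets had medians of 0.48 in KOC-7C, turning to -0.19 under quantile normalization, and -0.03 in TOV21G. Among them HMOX1 rose (mean 1.46), while TXNRD1 (-1.46) and OSGIN1 fell (1 higher and 2 lower of 21, over all genes and adjusted over the list alone). In the unfolded protein response list (medians 0.53 and 0.21, percentiles 68.7 and 97.1) PDIA4 fell, at -6.42 in KOC-7C, on the array with low 5' signal, and 0.68 in TOV21G (1 of 16, 1 adjusted over the list alone), and in the heat shock list (medians 0.42, turning to -0.13 under quantile normalization, and -0.23, percentiles 29.4 and 0.45) HSPA1B, at -3.67 in KOC-7C and -0.24 in TOV21G (1 of 15, 1 adjusted over the list alone). HSPA1A, in the same heat shock list, went the other way in KOC-7C (1.46, and -0.23 in TOV21G) and did not pass. Under control siRNA HSPA1A read -2.48 in KOC-7C and 3.99 in TOV21G, and HSPA1B 4.99 and 4.28. The probes of these copies were not checked for shared signal. Fatty acid synthesis (14 members, medians 0.56 and 0.30, percentiles 81.8 and 99.5), Polycomb repressive complex 2 (11, 0.70 and -0.04, percentiles 92.1 and 44.7, the latter 0.01 with normexp and quantile normalization) and the RNA interference machinery (13, 0.43 and -0.06) held no member that passed. CDK inhibitors had medians of 0.38 and 0.09 over 6 members, the latter -0.01 under scaling by the median, and CDKN1A fell (1 over all genes and 1 adjusted over the list alone). As for other cell types, leukocyte markers (medians 0.20 and 0.11) held 1 gene that rose, CD68, at 1.34 and 1.94. Endothelial markers had medians of 0.58 and 0.02 over 3 and 4 members, the latter -0.08 under scaling by the median, with none called, and no fibroblast marker was measured on both arrays of a line, although 1, COL1A1, was tested and rose (1 adjusted over the list alone).

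**Figure D3:**
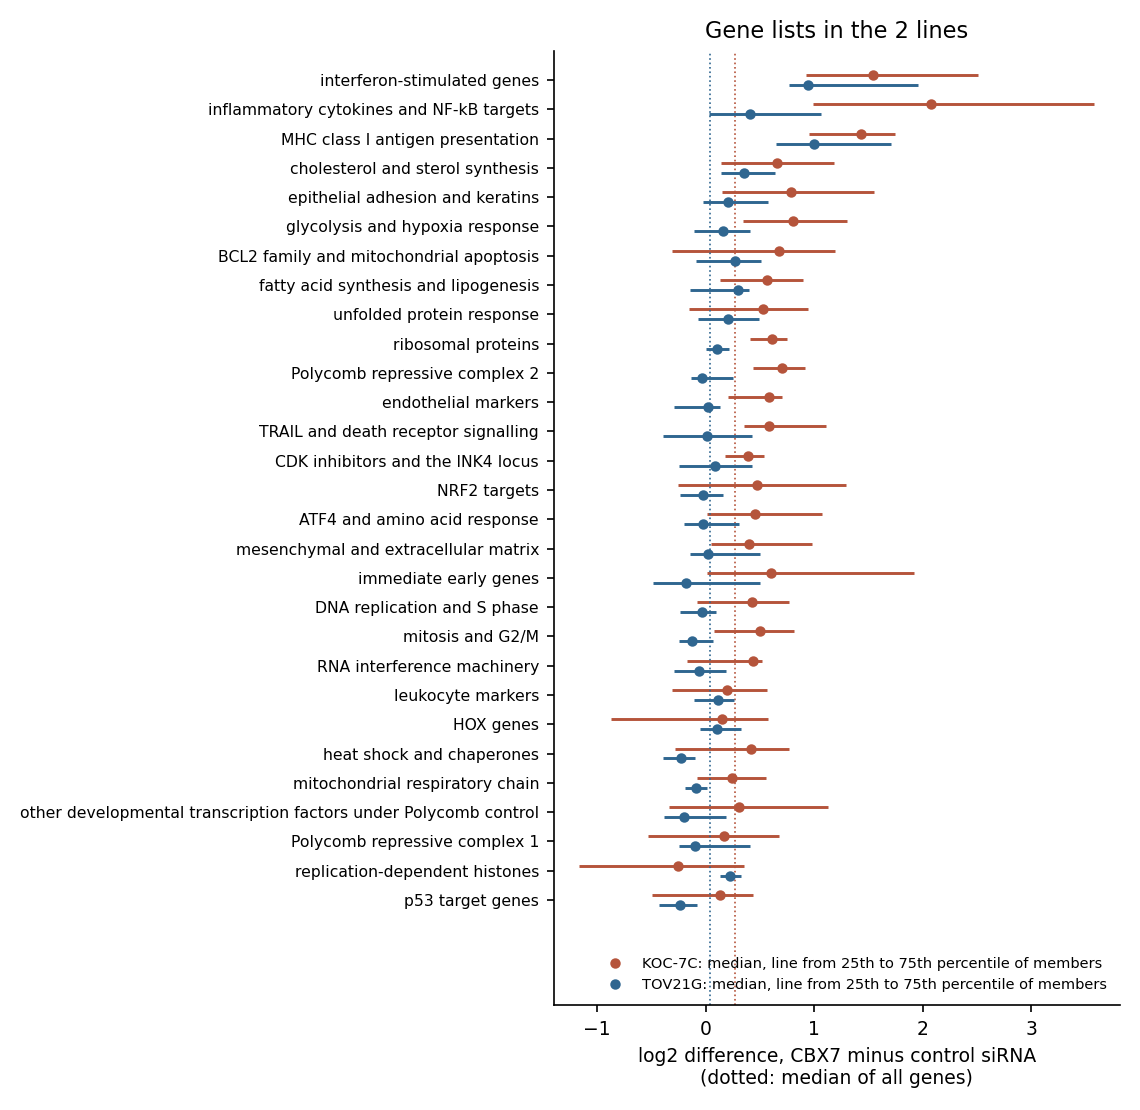
Median log2 difference (CBX7 minus control siRNA) of the measured members of 29 gene lists in KOC-7C and TOV21G, with a line from the 25th to the 75th percentile of the members. Interferon-stimulated genes (medians 1.55 and 0.94) and MHC class I genes (2.69-fold and 1.99-fold) lay above the median of all genes (0.27 and 0.03) in both lines.

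In TOV21G on its own, PGA3, a pepsinogen gene, was 24.8-fold higher with CBX7 siRNA and GSDMB 23.5-fold, followed by ACKR4 (21.7-fold), CSAG2 (20.4-fold), MX2, LGALS9C (15.8-fold), CCL5 (15.5-fold) and CSAG1 (14.9-fold). The lowest were SCEL (-2.74), an epithelial envelope protein, the growth factor NRG1 (-2.31), the thrombin receptor family member F2RL2 (-2.13), GSTA5 (-2.10), LYPD6B (-2.09), ACO1, DANCR (-1.86) and FAM107A (-1.82). NRG1 differed by 0.01 in KOC-7C. PGA3 was at least 17.3-fold higher in KOC-7C, where its control signal was not well above background, and F2RL2 was at least 1.95-fold lower there. Of 18694 genes measured in TOV21G, 577 were at least 2-fold higher and 100 at least 2-fold lower, with a median difference of 0.03. Under scaling by the median these counts were 466 and 164, a share of higher genes of 74.0% in place of 85.2%. A further 149 genes were at least 2-fold higher and 35 at least 2-fold lower as bounds.

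In KOC-7C the acute phase genes SAA2 (194-fold higher) and SAA1 (96.8-fold) led, with MMP1 (96.7-fold), TUBB3, a neuronal tubulin (61.5-fold), GSDMB (55.9-fold), CCL5 (43.5-fold), GBP5, an interferon-induced GTPase (42.6-fold), and ACKR4 (log2 difference at least 5.33). TUBB3 differed by -0.16 in TOV21G and MMP1 by 1.13. The lowest were PDIA4, a chaperone of the endoplasmic reticulum (-6.42), 28S ribosomal RNA (RNA28SN5, -5.61), CASP8 (-5.39), STT3A (-5.02), CDC42SE1 (-5.01), NUTF2 (-4.85), HAPLN2 (-4.82) and SNRNP40 (-4.80). In TOV21G these 8 lay between -0.58 (NUTF2) and 0.68 (PDIA4). Of 17255 genes measured in KOC-7C, 2572 were at least 2-fold higher and 1442 at least 2-fold lower. The median difference was 0.27, so counts above and below it are not symmetric about 0. The share of higher genes was 64.1%, against 54.5% under quantile normalization (1849 and 1542 genes) and 49.7% with normexp and quantile normalization (1081 and 1092). Bounds added 318 genes at least 2-fold higher and 227 at least 2-fold lower.

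Low 5' signal went along with the KOC-7C values. The 2964 genes were compared at their most 5' and most 3' probe. Of these, 529 of the 5' probes and 142 of the 3' probes were at least 2-fold lower in KOC-7C, against 20 and 9 in TOV21G. At least 2-fold higher were 220 of the 5' and 540 of the 3' probes in KOC-7C, against 39 and 69. The gap grew with the distance between the probes, from -0.11 up to 500 bp to -0.69 over 20000 bp in KOC-7C, and from -0.03 to -0.18 in TOV21G.

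**Figure D4:**
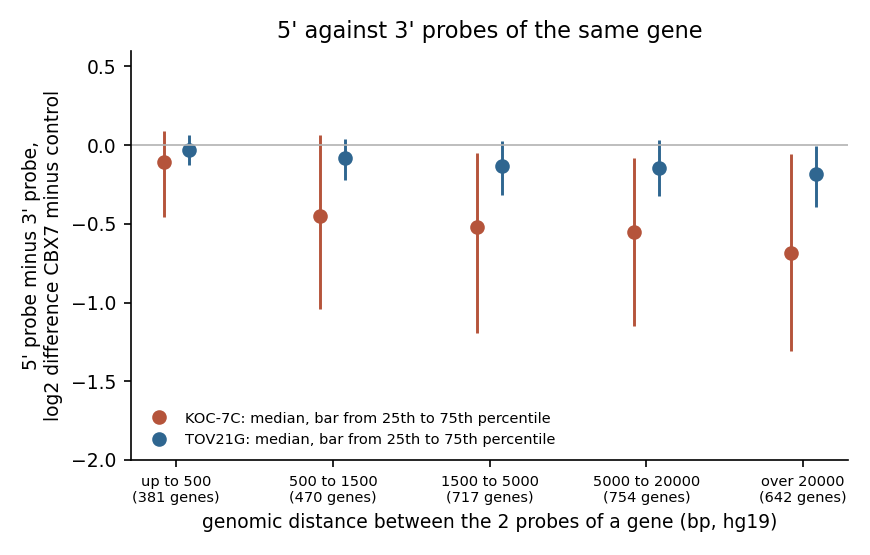
Difference between the 5' and the 3' probe of the same gene in their log2 difference (CBX7 minus control siRNA), by the genomic distance between the probes, for KOC-7C and TOV21G (median, bar from the 25th to the 75th percentile of genes). The KOC-7C median went from -0.11 up to 500 bp to -0.69 over 20000 bp.

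The agreement of the lines was set over the 16928 genes measured on all 4 arrays, across genes, which are not independent replicates. The log2 differences of KOC-7C and TOV21G correlated with Pearson's r of 0.39 and Spearman's rho of 0.34, and 59.1% of genes had the same sign. At least 2-fold higher in both were 354 genes, against 70.6 for independent lists, and 74.1% of the genes higher in TOV21G were also higher in KOC-7C. At least 2-fold lower in both were 31 genes, against 6.68. In opposite directions by at least 2-fold were 12 genes, among them IFI6, TMEM151B (-2.08 in KOC-7C and 1.22 in TOV21G), LYNX1-SLURP2 (-1.33 and 1.16, although the mean of its probes gave 1.20 in KOC-7C), KIF12 (-1.53 and 1.08) and 18S ribosomal RNA (RNA18SN5, -2.97 and 1.04).

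The control arrays show how far the lines lay apart under control siRNA. Of 18737 genes measured on both, 73 were at least 4-fold higher in KOC-7C and 203 at least 4-fold higher in TOV21G, and log2 signals correlated with r = 0.98 across genes. Of the line-specific genes measured on all 4 arrays, 67 of 68 kept the side of KOC-7C and 174 of 184 the side of TOV21G between the CBX7 siRNA arrays. The KOC-7C CBX7 siRNA array correlated with its control at r = 0.953, less than the control arrays of the 2 lines with each other (0.978), and the TOV21G arrays correlated at 0.988. The value of 0.953 involves the array with low 5' signal, so it cannot tell an effect of the siRNA from one of that signal.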

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

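All tests of explanations in this part were chosen only after the result was seen. Each gene here had a value in KOC-7C opposite in sign to that in TOV21G, by an amount given as KOC-7C minus TOV21G on the log2 scale. With 1 array per group the difference between the lines was not tested. Of the named interferon-stimulated genes IFI6 differed by -4.20 (-2.44 in KOC-7C, 1.76 in TOV21G). Ribosomal RNA differed by -6.12 (RNA28SN5) and -4.01 (RNA18SN5). The endoplasmic reticulum chaperone gene PDIA4 differed by -7.10. The matrix linker gene HAPLN2 differed by -5.38. The cardiac transcription factor gene NKX2-5 differed by -4.42. The mitochondrial apoptosis gene DIABLO differed by -3.61, although its other probe was -0.12 in KOC-7C and 0.09 in TOV21G. The triglyceride synthesis gene DGAT2 differed by -2.57. The homeobox gene HOXB3 differed by -2.46. The B-cell gene CD79A differed by -1.16. TMEM151B differed by -3.30, KIF12 by -2.61 and LYNX1-SLURP2 by -2.50, although the mean of the LYNX1-SLURP2 probes gave 1.20 in KOC-7C, and another of its probes 3.93 in TOV21G. All 13 were the lower of the pair in KOC-7C, and all lay more than 0.25 from 0 in both lines. Named genes of opposite sign that lay nearer 0 in TOV21G are not listed here, and they went both ways. TUBB3 (5.94 in KOC-7C and -0.16 in TOV21G) and CDKN1C (1.97 and -0.17) were higher in KOC-7C, and CASP8 (-5.39 and 0.02) was lower. The shared direction of the 13 therefore holds under that limit only.

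Differences were larger in KOC-7C than in TOV21G (SD over genes 0.94 and 0.45). Scaling of the dimmer CBX7 siRNA arrays is argued against, since the ratio of these SDs was 1.99 under quantile normalization. Loss of 5' signal in the KOC-7C CBX7 siRNA sample is a candidate cause of part of it, as 5' probes were at least 2-fold lower 3.73 times as often as 3' probes of the same genes, and 3' probes at least 2-fold higher 2.45 times as often. The probes for 28S ribosomal RNA, lower by 4 log2 units or more on that array alone, and a correlation of the difference with probe GC content (r = -0.28 across probes in KOC-7C, 0.08 in TOV21G) were seen beside it. With the probe nearest the 3' end of each gene, the SDs were 0.94 and 0.46 (ratio 2.06). KOC-7C then had 2625 genes at least 2-fold higher and 1416 lower, but only genes with more than 1 probe could change in that setting. Among 3' probes alone, 540 were at least 2-fold higher and 142 lower in KOC-7C, against 69 and 9 in TOV21G. Larger differences in KOC-7C were thus also seen at 3' probes. These counts cannot separate loss of 5' signal from a response, since the 540 higher 3' probes also enter the 2.45 above. A stronger response of KOC-7C cells stays open and untested.

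The CBX7 probes gave unequal differences (-1.35 and -0.56 in KOC-7C, -1.28 and 0.17 in TOV21G). Loss of 5' signal is argued against, since it would lower the 5' probe more, and that probe lay above the 3' probe by 0.80 in KOC-7C and 1.45 in TOV21G (percentiles 94.1 and 99.9 of 2964 probe pairs). Transcript forms that lack the 3' region, or signal of another transcript at the 5' probe, were not tested.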

How the results depend on the processing

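The probe nearest the 3' end of each gene was chosen as an alternative only after the data were seen. Of the alternative values of the summary results 124 stayed the same, 29 were weaker, 11 stronger, 7 moved and 1 reversed. The counts that moved follow, for KOC-7C higher, KOC-7C lower, TOV21G higher and TOV21G lower. With no filter on background they were 4837, 2428, 1939 and 838, at 1.5-fold 5659, 2732, 1901 and 832, and at 3-fold 705, 653, 164 and 10, as a wider or narrower selection must give. With normexp and quantile normalization 1081 were higher in KOC-7C, 291 higher and 36 lower in TOV21G, and with median scaling 164 were lower in TOV21G. For genes higher and lower across both lines, limma called 0 and 0 with normexp and quantile normalization, 0 and 0 with quantile normalization, 150 and 7 with the mean of all probes, 0 and 0 without the replicate block (a block here is the cell line), and 0 to 0 when each array was left out in turn, which drops the block and assumes that the lone array varies like the others. The block takes out the difference between lines, and the prior degrees of freedom were 54.8 with the main scaling, 3.78 with quantile normalization and 3.14 with normexp, and the prior residual SD was 0.43, 0.32 and 0.21, with no fit holding one of these fixed. Genes at least 2-fold higher in both lines were 211 and lower 15 with normexp and quantile normalization, and 811 and 121 with no filter. Control arrays 4-fold apart with normexp numbered 25 higher in KOC-7C and 98 in TOV21G. Lists below random lists in both lines, 1 in the main setting (mitochondrial respiratory chain), were 0 with the probe nearest the 3' end and 0 with no filter. CBX7 was -0.95 in KOC-7C and -0.56 in TOV21G with the mean of its probes, and -0.56 and 0.17 with the other probe alone, the latter reversed. TNFSF10 was 3.21 and 2.63 with normexp and quantile normalization, and 4.35 and 3.4 with its other probe. Among named genes, 1796 of 2079 values stayed within 0.25 (log2) of the value reported and 2 reversed with the mean of all probes, H2AC6 (-1.32) and LYNX1-SLURP2 (1.20) in KOC-7C. The cause was not tested unless stated.

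The sign of the median turned under another scaling for 6 of 30 lists in each line, and not for interferon-stimulated, MHC class I or inflammatory genes. Signal over background limits the values: 1866 genes of KOC-7C and 1404 of TOV21G were above background on the control array alone, and where the CBX7 siRNA array is dim a fall is given only as a bound.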

Other observations

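Of 7 further gene groups, chosen after the data were seen, 5 were above random lists in both lines. The interferon genes themselves were measured, with IFNB1 at 2.30 in KOC-7C and 0.99 in TOV21G, IFNL1 at 3.14 and 1.82, IFNL2 at 2.93 and 1.45 and IFNL3 at 2.36 and 1.36, and limma called all 4. Of the guanylate binding proteins, 5 of 6 rose, from GBP2 (2.59 and 1.67) to GBP5 (5.41 and 2.87), and GBP6 (-0.45 and 0.20) did not pass. MHC class II genes had medians of 1.51 in KOC-7C and 2.03 in TOV21G over 8 members, and 6 of 10 tested rose, among them the regulator CIITA (2.69 and 2.22) and HLA-DPA1 (3.05 and 3.50). Receptors and enzymes that sense double-stranded RNA had medians of 1.05 and 0.88 over 9 members. These medians equal the values of EIF2AK2 in KOC-7C and OAS1 in TOV21G, which also belong to the interferon-stimulated list. In this group 4 rose, TLR3 (1.43 and 1.51), RIGI (mean 1.98), IFIH1 (mean 2.02) and OASL (mean 3.14), of which the last 3 also belong to that list. The group is therefore not independent of the interferon-stimulated list.

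Complement and acute phase genes had medians of 2.32 in KOC-7C over 18 members and 0.62 in TOV21G over 22, and 13 of 23 tested rose. CFB differed by 3.76 and 2.57, C3 by a mean of 2.64 and C1R by 2.70 and 2.51, while the fibrinogen genes FGB (3.93 and 0.53) and FGG (4.46 and 0.60) were higher mainly in KOC-7C, the line whose CBX7 siRNA array had low 5' signal. Among 16 glutathione transferases GSTA2 and GSTA5 fell and none rose, with medians of 0.36 and 0.18 (percentiles 42.5 and 92.4). In the APOBEC3 family 1 of 6 tested genes rose, APOBEC3G, by a mean of 3.55, and the medians were 0.21 and 0.24 (percentiles 58.7 and 86.7).

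All tests of explanations in this part were chosen only after the result was seen. Interferon-stimulated genes and TNFSF10 were higher in both lines. Scaling of the dimmer arrays is argued against by the smaller of the line medians of the list, 0.966 with normexp and quantile normalization. How far the low 5' signal of the KOC-7C CBX7 siRNA array shaped the values of the list in that line was not tested. Whether the genes responded to loss of CBX7 or to the siRNA itself cannot be told apart, because the arrays hold 1 CBX7 siRNA condition against 1 control, and both readings allow the higher interferon genes (median of the smaller difference 1.41).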
